A study of Homo sapiens with 14 samples.

How the data were processed

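RNA polymerase II (RNAPII) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in BJ hTERT cells, a line of human foreskin fibroblasts immortalised with telomerase. There were 14 libraries in 14 groups, 1 library per group, from an antibody against total RNAPII or against RNAPII phosphorylated at serine 2 of its C-terminal repeats (Ser2). Each antibody was used at 14 h without a treatment name, and at 16, 19 and 22 h in cells given DMSO, the vehicle, or an ATR inhibitor (ATRi). What the hours count from, the inhibitor and any cell synchronisation are not stated. The protocol text names antibodies against a phosphorylated histone and histone H3 only, so the antibody identity rests on the sample descriptions.

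The deposited table holds 12425 genes with reads per 1000000 library reads (RPM) over the whole gene span, as computed by the authors and not divided by gene length. Per the submitters' processing notes, reads were mapped with Bowtie2 2.3.3.1 and handled with SAMtools 1.4 on hg38. The counting tool, the annotation, the choice of genes and any treatment of duplicates, input or spike-in are not stated. Input or spike-in values were not used here. Without a spike-in, a gain over all genes cannot be separated from a more efficient immunoprecipitation. Every value was a whole multiple of a step within its column (tolerance 0.01 reads, 100.0% of values), so whole reads and the library total behind each column were recovered. These totals were 17181179 to 62368915 reads. The median gene held 303 to 1623 reads, and 3 reads corresponded to 0.048 to 0.175 RPM, a floor for counting error only.

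The table gives Ensembl identifiers. Gene symbols were assigned by position against the RefSeq genes of GRCh38: the best mutual overlap had to reach a Jaccard index of 0.8, or 0.5 with an end within 100 bp. This named 10735 genes (86.4%). Of 20 identifiers checked by hand, 19 received a name and all 19 names were right. Reads over a gene that overlaps others cannot be assigned to it alone. The 14 mitochondrial genes were left out of all comparisons.

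With no replicates, hours served as blocks. The ATRi to DMSO difference was tested within each antibody over its 6 treated libraries with hour as a block, so the residual is the departure of the 3 hourly differences from their mean. Ser2 relative to total was tested over the 12 treated libraries with antibody-by-hour blocks. The 22 h to 16 h change was tested within each antibody with treatment as a term, so the DMSO and ATRi libraries of an hour stand in for replicates. Tests used limma 3.58.1 (eBayes with trend, two-sided) in R 4.3.3 on log2(RPM + 0.5), for genes with a mean of at least 1 RPM, at a Benjamini-Hochberg adjusted p threshold of 0.05. P-values of these gene tests measure only the spread between these libraries. The SE of a single gene is the moderated one of limma, drawn towards the spread of genes of like level. It is therefore not the SE of that gene's pairs alone, and in the 22 h to 16 h test the 19 h libraries enter it as well. Signs flipped over 3 hours cannot give an exact two-sided p below 0.25 for any single quantity. Tested on simulated data with 50 genes changed 2-fold, the limma fits recovered 48 for ATRi in total RNAPII, 50 for ATRi in Ser2, 43 for the difference, 36 for the hours in total RNAPII and 50 for the hours in Ser2. At 1.25-fold they recovered 0, 31, 1, 1 and 14. The simulated noise was independent between genes with a common spread and lacked the shifts that many genes share in these data. These counts therefore do not give the recovery in the real libraries.

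Lists of genes were tested with camera (preset inter-gene correlation of 0.01, then an estimated one) and with fry, adjusted over the lists of each comparison. With the preset correlation, camera sets list members against other genes and takes genes as nearly independent. Its small p-values therefore rest on the spread between genes and not on replicate libraries. The estimated correlation and its test instead rest on the few degrees of freedom that these libraries leave. A list could hardly pass that test, so a call lost there neither upholds nor refutes the list. There were 18 lists: replication-dependent histones, G1/S and DNA replication, G2/M and mitotic, p53 targets, immediate early, ribosomal proteins, DNA damage checkpoint and repair, fibroblast matrix and contractile, common fragile site and very long genes, spliceosomal snRNAs, RNAPII transcription machinery, NF-kB and interferon response, ATF4 and unfolded protein response, cholesterol synthesis, heat shock, keratinocyte markers, endothelial and blood cell markers, and silent tissue-specific genes. Lists with fewer than 5 measured members were not tested: keratinocyte markers had 1, endothelial and blood markers 2 and silent genes 2. For each pair of libraries, a list median was placed among 10000 random lists matched on mean level in 10 bins, and intervals at 95% came from 1000 resamples.

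Groups, comparisons, lists, the rule for named genes and the other settings to try were fixed before the data were examined. Under that rule, up to 10 genes higher and 10 lower per ATRi comparison were ranked by the smallest of the 3 hourly log2 ratios in absolute size, with the same sign at every hour, among genes above the median level. The comparisons of hours and of antibodies took up to 5 each way, and each list its 2 to 4 members with the largest change. POLR2A, ATR, CHEK1 and CDKN1A were always included. Genes without a symbol under that rule are not described.

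The other settings fixed in this way were quantile normalization, median centring, no filter on low values, limma without trend, pseudocounts of 0.05 and 5 RPM, leaving out each hour, no hour block and 1 joint fit. Further ones were chosen after seeing the data. These were edgeR 4.0.16 (quasi-likelihood, with TMM or library totals) and DESeq2 1.42.0 on recovered reads, subtraction of a background density, removal of each library's loess trend with read density (span 0.3), and random lists matched on length as well. The background density was the percentile 1 of RPM per kb over genes of at least 30 kb. The planned subtraction of silent genes was not run because 2 were measured. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.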

Results

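RNAPII occupancy was profiled by ChIP-seq in BJ hTERT fibroblasts with and without inhibition of ATR, the kinase that answers replication stress. The study names S phase as its subject, but the cell cycle phase at each hour is not stated. The 14 libraries were single samples of their groups, so no value within a group carries an error. The total RNAPII libraries held 17181179 reads at 14 h, 26482785 (DMSO) and 19273038 (ATRi) at 16 h, 35871568 and 46533646 at 19 h, and 18787183 and 23928707 at 22 h. The Ser2 libraries, which follow the elongating form, held 18152431 reads at 14 h, 38269525 (DMSO) and 19539110 (ATRi) at 16 h, 30193468 and 36316086 at 19 h, and 30838523 and 62368915 at 22 h.

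The share of reads within the listed nuclear genes differed between libraries. In total RNAPII it was 72.0% (DMSO) and 70.8% (ATRi) at 19 h, against 42.8% and 57.4% at 22 h. In Ser2 it was 63.5% and 65.6% at 19 h, and 40.0% and 44.3% at 22 h. List values are therefore given relative to the median of all genes where this is said, and single-gene values and counts of genes on the deposited scale.

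**Figure D1:**
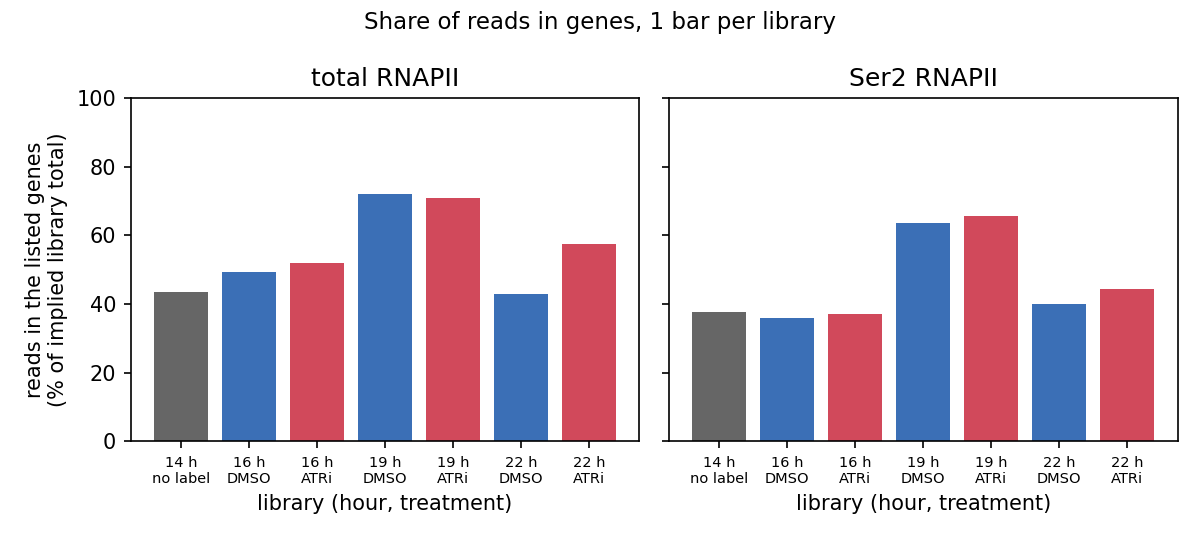
Reads within the listed nuclear genes as a percent of the library total, 1 bar per library, for total RNAPII and Ser2 RNAPII by hour and treatment. Both antibodies have their highest shares at 19 h, and the 22 h total RNAPII pair differs most between DMSO (42.8%) and ATRi (57.4%).

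The comparison of ATRi with DMSO over 16, 19 and 22 h asked which genes gained or lost total RNAPII alike at the 3 hours. Mitotic genes lay above the other genes: 38 of 39 had a larger mean ATRi to DMSO ratio than the median gene, and their median was 0.17 above it (log2). The list was near the median gene at 19 h, however, at 0.02 above it. There 23 of 39 were above the median gene and 18 of 39 had a log2 ratio above 0. PLK1, the mitotic kinase, had log2 ratios of 0.48, 0.02 and 0.96 at 16, 19 and 22 h, CCNB1 (cyclin B1) 0.53, 0.06 and 0.82, ASPM, a spindle pole protein, 0.44, 0.06 and 0.91, and ANLN, the cytokinesis protein anillin, 0.23, 0.07 and 1.04. Fibroblast matrix and contractile genes lay 0.13 above the median gene, with 25 of 27 above it, but at 19 h only 1 of 27 was above (list at -0.15). Among these, LUM (lumican) had ratios of 0.37, -0.15 and 1.61, COL1A2, a type I collagen chain, 0.40, -0.10 and 1.24, and FN1 (fibronectin) 0.44, -0.12 and 1.17.

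Immediate early genes lay 0.12 above the median gene (16 of 18 above), for example CCN2 with a mean log2 change of 0.41, ZFP36 with 0.40 and DUSP1 with 0.37. At 19 h, however, only 2 of 18 were above (list at -0.16), and the list lay the other way once the trend with read density was removed. Common fragile site and very long genes lay below, with 3 of 17 above the median gene, and their largest changes went both ways (TCF4 0.24, FNDC3B 0.23, PDE4D -0.20 and LPP 0.18). The side of this list too turned when that trend was removed or 22 h was left out. In the test with camera, the adjusted p was 4.0e-12 for mitotic genes, 2.9e-08 for matrix genes, 0.0024 for immediate early genes, 5.5e-04 for fragile site genes and 0.046 for the transcription machinery (CDK9 0.41, PAF1 0.39). All 5 calls were lost at an adjusted p = 0.930 with an estimated correlation. Without 22 h the calls of matrix genes (camera adjusted p = 0.327), immediate early genes (0.925), fragile site genes (0.960) and the machinery (0.960) ended, and that of immediate early genes also without 16 h (0.0848). For fragile site genes the median (0.05), the mean (0.03) and fry were above 0 while camera placed the list below other genes. The camera adjusted p was 0.103 for histones, 0.714 for G1/S genes, 0.129 for p53 targets, 0.139 for ribosomal protein genes, 0.529 for DNA damage genes, 0.103 for snRNAs, 0.272 for the NF-kB list, 0.0913 for the ATF4 list, 0.128 for cholesterol synthesis and 0.331 for heat shock genes.

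In total RNAPII 17.9% of 12000 genes were higher in ATRi at all 3 hours and 1.3% lower (8.3% and 6.9% after centring each hour), where independent signs would give 25.0% in all. Single genes with the same sign at each hour included USP53 (ENSG00000145390, hg38 chromosome 4, 119212587 to 119295517), a tight junction protein gene. It had ratios of 0.50, 0.23 and 1.15 and a mean of 0.63 ± 0.19 (moderated SE, n = 3 pairs). NTN4 (netrin 4) had a mean of 0.43, MYOCD (myocardin) 0.25, SCN9A, a sodium channel gene, 0.26, PRICKLE1 0.20, FHIP2A 0.35, EXOC1 0.24 and TRAPPC13 0.20. On the lower side, DPF3, a chromatin remodelling subunit, had a mean of -0.18, KIF26B -0.17, FRMD3 -0.16, OSBPL10 -0.12, MBOAT2 -0.11, TRIM2 -0.10, MSRA -0.07 and SFMBT1 -0.04. ATR itself had 0.01, CHEK1, the kinase it activates, 0.23, POLR2A, the gene of the largest RNAPII subunit, 0.26 and CDKN1A, which encodes the inhibitor p21, 0.34. By limma, 0 of 12031 genes passed higher and 0 lower; 204 had an unadjusted p under 0.05, all of them higher, against 35 higher and 31 lower with median centring. edgeR and DESeq2 also called 0, with 51 and 57 genes at an unadjusted p under 0.05. Subtraction of a background density gave 21 higher and 35 lower. The median gene lay at 0.18, a shift that was 0.02 without 22 h.

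In Ser2, immediate early, matrix, mitotic and ATF4 genes had larger mean ATRi to DMSO ratios than other genes, but not at every hour: at 19 h immediate early genes lay at -0.05 relative to the median gene (6 of 18 above) and matrix genes at -0.07 (5 of 27). Immediate early genes lay 0.16 above the median gene (16 of 18 above it), with FOSL1 at a mean log2 change of 0.37, JUN at 0.32, DUSP6 at 0.30 and NR4A1 at 0.25. Matrix and contractile genes lay 0.10 above (21 of 27), with the tropomyosin genes TPM1 at 0.42 and TPM2 at 0.40, though the list lay below other genes once the trend with read density was removed. Mitotic genes lay 0.06 above (33 of 39), with CDC20, the activator of the anaphase-promoting complex, at 0.41, and the kinase gene AURKA at 0.29. Unfolded protein response genes of the ATF4 list lay 0.13 above (11 of 15), with SDF2L1 at 0.37, XBP1 at 0.34 and HERPUD1 at 0.31. Spliceosomal snRNA genes lay 0.20 below, with 0 of 7 above the median gene, but the other way without 22 h, and fragile site genes 0.10 below, with 1 of 17 above. With the trend with read density removed, the camera adjusted p was 0.338 for immediate early genes, 0.459 for mitotic genes, 0.338 for the ATF4 list and 0.187 for fragile site genes, so these calls ended.

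The camera adjusted p was 4.1e-04 for immediate early genes, 4.8e-04 for matrix genes, 5.6e-04 for mitotic genes, 0.010 for the ATF4 list, 4.1e-04 for snRNAs and 4.1e-04 for fragile site genes. All 6 calls were lost at an adjusted p = 0.902 with an estimated correlation. Without 16 h the calls of immediate early genes (camera adjusted p = 0.140), matrix genes (0.914) and the ATF4 list (0.140) ended, and without 22 h those of mitotic genes (0.111) and snRNAs (0.267). Adjusted over the list alone, 13 immediate early, 14 matrix, 5 mitotic, 10 ATF4-list and 4 p53 target genes passed higher, against 0 over all genes tested. A short list is adjusted less than all genes are. By limma on this scale, 2630 of 11989 genes were higher at an unadjusted p under 0.05, against 632 with median centring. These counts alone therefore do not show gains particular to the lists. The list of NF-kB genes had 1 adjusted over the list alone, and its camera adjusted p was 0.982. For p53 targets that p was 0.185, with CDKN1A at 0.42, BBC3, which encodes the apoptosis factor PUMA, at 0.34 and GADD45A at 0.30. It was 0.924 for histones, 0.185 for G1/S genes, 0.251 for ribosomal protein genes, 0.562 for DNA damage genes, 0.0508 for the transcription machinery, 0.475 for cholesterol synthesis and 0.129 for heat shock genes.

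In Ser2 42.6% of genes were higher in ATRi at all 3 hours and 3.4% lower (16.0% and 16.8% after centring). The single genes ranked highest in Ser2 by the smallest of their 3 hourly ratios were SEMA7A, a semaphorin gene, and SLC2A1, the glucose transporter GLUT1. SEMA7A (ENSG00000138623, chromosome 15, 74409289 to 74434467) had a mean log2 change of 0.46 ± 0.08 (moderated SE, n = 3 pairs, limma adjusted p = 0.0824). SLC2A1 had 0.37 ± 0.07 (moderated SE, n = 3 pairs, limma adjusted p = 0.0824). ARLN lay at 0.39, KCTD20 at 0.30, ARF1 at 0.30, PEX10 at 0.29, USP53 at 0.28, UBE2J2 at 0.27 and UGCG, the glucosylceramide synthase, at 0.26. ARLN starts at 119296419 on chromosome 4, just past the end of USP53 at 119295517, so their values may not be separate. PEX10 shares 15.1% of its span with another gene. Lower values were those of SCN3A at -0.21, TNIK at -0.17, COL24A1 at -0.17, CCDC148 at -0.15, PPP1R9A at -0.14, FAM171B at -0.14, CACHD1 at -0.14, MAP7 at -0.14 and ADGRL2 at -0.13. POLR2A lay at 0.17, CHEK1 at 0.11 and ATR at 0.06. By limma, 0 of 11989 genes passed in either direction; 2655 had an unadjusted p under 0.05, of which 2630 were higher, but with median centring 632 were higher and 786 lower. edgeR called 0, with 522 higher and 712 lower at an unadjusted p under 0.05. DESeq2 called 0 higher and 16 lower, but its filter left 10924 genes without an adjusted p, so this count does not compare with the others. Without 19 h limma called 846 higher and 0 lower, without 16 h 38 higher and 6 lower, and without 22 h 0, so the count rests on which hours are included.

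Whether Ser2 moved apart from total RNAPII under ATRi was asked with the 12 treated libraries together. Mitotic genes had a smaller ATRi effect in Ser2 than in total RNAPII: 5 of 39 lay above the median gene, and their median lay at -0.13 relative to it. CCNB1 had a difference of -0.35, PLK1 of -0.34, and the kinesin genes KIF20A and KIF2C of -0.30 and -0.28. At 16, 19 and 22 h the list lay 0.198, 0.019 and 0.319 above the median gene in total RNAPII. In Ser2 it lay 0.055, 0.014 and 0.140 above, so the antibodies differed little at 19 h. Reads in genes were also a lower share in Ser2 (at 16 h 35.8% in DMSO and 37.1% in ATRi, against 49.4% and 52.0%). The part of this in the difference was not tested. The camera adjusted p was 1.8e-07, lost at an adjusted p = 0.975 with an estimated correlation. The other 14 lists tested were not called, the nearest being matrix genes at 0.0911, with LUM at -0.62. This number rests on the hours and the scaling: 6, 7 and 5 lists were called without 16, 19 and 22 h, and 2 with centring, quantile normalization or the trend with read density removed. The median gene went from -0.06 to 0.05 without 22 h. Among single genes, HMGA1, a chromatin architectural protein gene, lay at 0.35, SMIM29 at 0.35, SPRY4 at 0.28, GNPDA2 at -0.15, SAMTOR at -0.15 and TTC3 at -0.14. SMIM29, SPRY4 and GNPDA2 share 29.2%, 11.6% and 42.2% of their spans with other genes. SMIM29 starts at 34246380 on chromosome 6, just past the end of HMGA1 at 34246231, so their values may not be separate. By limma, 0 of 12013 genes passed; 9 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0, with 27 and 7.

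The 22 h to 16 h comparison asked how occupancy differed between hours in both treatments. Each hour was sampled in 1 DMSO and 1 ATRi library per antibody. The hour therefore cannot be told from anything else that its libraries shared, and the p-values do not cover this. In total RNAPII, G1/S and DNA replication genes lay 0.48 below the median gene, with 1 of 42 above it, and mitotic genes lay 0.44 above, with 39 of 39 above. E2F1, the transcription factor of G1/S genes, had a log2 change of -2.01 in DMSO and -0.81 in ATRi, and the replicative helicase genes MCM3 and MCM6 had means of -0.99 and -0.96. KIF2C lay at 0.77, AURKB, a kinase of chromosome segregation, at 0.64 and CCNB1 at 0.64. The camera adjusted p was 4.2e-36 for G1/S genes and 6.1e-32 for mitotic genes, both lost at an adjusted p = 0.917 with an estimated correlation. Matrix genes lay 0.23 below (camera adjusted p = 1.0e-06; LUM -1.34). Histones lay 0.13 above (camera adjusted p = 0.0080), the NF-kB list 0.06 above (0.0198; PTGS2 0.72), immediate early genes 0.06 below (0.0257; KLF4 -0.95) and ribosomal protein genes 0.09 below (0.0423), though at -0.44 in the DMSO pair and 0.27 in the ATRi pair. The ATF4 list was called higher (0.0080) with a mean of 0.10 but a median of -0.03, and relative to the median gene it lay at -0.07 in the DMSO pair and 0.23 in the ATRi pair. Its member HSPA5, the chaperone BiP, lay at 0.69. These 6 calls too were lost at an adjusted p = 0.917 with an estimated correlation.

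Other genes with the same sign in both treatments were HAS2, a hyaluronan synthase gene, at a mean of 1.12 (2.17-fold; 0.75 in DMSO and 1.49 in ATRi), FIBP at 0.92, MMP1, a collagenase gene, at 0.87, CCNF at 0.86 and FAM167A at 0.75. On the lower side were CDC45, a part of the replication fork helicase, at -0.93, PLXND1 at -0.86 and SGSM2 at -0.68. By limma, 0 of 12031 genes passed; 355 had an unadjusted p under 0.05, of which 283 were lower, against 477 higher and 560 lower with median centring. Limma called 491 higher and 555 lower once the trend with read density was removed. Adjusted over the list alone, 20 G1/S genes, 2 matrix genes and 1 immediate early gene passed lower. edgeR called 0 (991 at an unadjusted p under 0.05) and DESeq2 24 higher and 26 lower, with 933 genes left without an adjusted p.

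In Ser2, all 39 mitotic genes measured rose from 16 h to 22 h, by a median of 0.70, which is 0.49 above the median gene, and 32 were called higher with median centring. AURKB (ENSG00000178999, chromosome 17, 8204733 to 8210600) rose by 1.27 ± 0.11 (moderated SE, 2 pairs, limma adjusted p = 1.2e-06). Its signal went from 9.20 to 20.9 RPM in DMSO and from 9.98 to 27.0 RPM in ATRi. KIF2C rose by 1.02, CDC20 by 0.97 and CCNB1 by 0.96. Of the 42 G1/S genes, limma called 6 lower and 5 higher (22 lower and 0 higher with median centring), and the list lay 0.24 below the median gene. By direction alone, 11 of 42 were above 0 in the DMSO pair and 22 of 42 in the ATRi pair. E2F1 (ENSG00000101412, chromosome 20, 33675683 to 33686404) fell by 0.66 (limma adjusted p = 2.3e-04), MCM6 fell by 0.49 and MCM2 fell by 0.37, while FEN1, which shares 96.2% of its span with other genes, rose by 0.52.

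Of all genes tested, 39.0% passed higher on the deposited scale, so the counts of lists are also given with median centring. In these counts, genes that rose or fell are those past the adjusted threshold by limma, not all that moved that way. Replication-dependent histone genes rose in 18 of 23 cases (11 with centring), among them H1-3 by 0.87 and H3C11 by 0.78. Ribosomal protein genes rose in 50 of 60 (12 with centring), for example RPL28 by 0.68 and RPL9 by 0.63, although the list lay on the other side of the remaining genes once the trend with read density was removed. Of the ATF4 list, 10 of 15 rose (6 with centring), with HSPA5 at 1.18, XBP1 at 0.96 and HERPUD1 at 0.78. The cytokine gene IL6 rose by 1.19 and PTGS2, the inducible cyclooxygenase, by 1.23, among 7 of 17 NF-kB genes (6 with centring, and 2 lower). Immediate early genes rose in 9 of 18 (EGR1 by 0.93, FOSL1 by 0.77) and 1 fell, with 6 higher and 2 lower after centring. Matrix genes rose in 15 of 27 (COL6A3 by 0.78) and 2 fell, of which LUM fell by 0.56, with 4 higher and 3 lower after centring. On the deposited scale 7 of 21 p53 targets rose (MDM2 by 0.56) and 1 fell, 13 of 29 DNA damage genes rose (H2AX by 0.65), 19 of 39 machinery genes (HEXIM1 by 0.60, POLR2A by 0.42), 4 of 16 cholesterol genes (STARD4 by 0.48) and 5 of 10 heat shock genes (HSPA8 by 0.59). With centring these were 2 higher and 2 lower, 1 and 0, 2 and 1, 0 and 3, and 1 and 0, so most of these rises were not kept. Of fragile site genes 3 rose and WWOX fell by 0.35 (0 higher and 7 lower with centring), and of 7 snRNAs only RNU4-1 rose, by 0.36 (0 with centring).

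The camera adjusted p was 1.4e-19 for mitotic genes, 9.5e-11 for G1/S genes (lower), 2.6e-05 for ribosomal protein genes, 7.6e-05 for histones, 0.0041 for fragile site genes (lower, while fry gave higher), 0.0139 for the ATF4 list and 0.0189 for snRNAs (lower, though their median lay 0.32 above that of all genes in the DMSO pair and at -0.82 in the ATRi pair). Relative to the median gene, ribosomal protein genes lay at 0.01 in the DMSO pair and 0.40 in the ATRi pair, and histones at 0.58 and 0.09, so each of these rests mostly on 1 pair. All 7 calls were lost at an adjusted p = 0.758 with an estimated correlation. FIBP rose by 1.34 and CCNF, which encodes cyclin F, by 1.20, while MGMT, a DNA repair methyltransferase gene, fell by 0.32, CDH8 fell by 0.31 and SUMF1 fell by 0.29. CHEK1 lay at 0.21, CDKN1A at 0.33 and ATR at 0.09, none past the threshold. By limma, 4678 of 11989 genes passed higher and 110 lower, around a median gene at 0.21. With median centring the counts were 1221 and 1262, with edgeR 1160 and 911 and with DESeq2 623 and 597 (2092 genes without an adjusted p), so the excess of higher genes was not kept under these scalings.

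**Figure D2:**
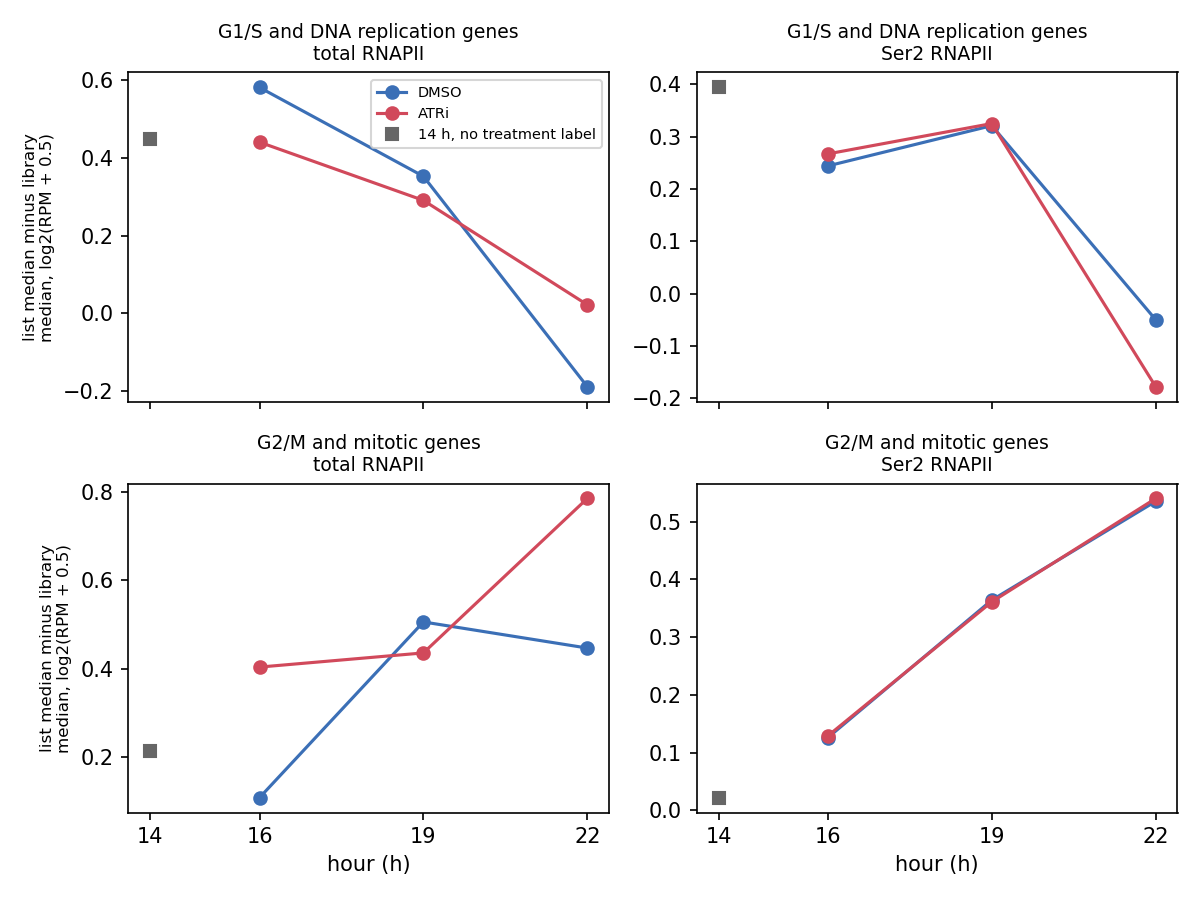
Median log2(RPM + 0.5) of the G1/S and the mitotic list minus the library median, by hour in h, for total and Ser2 RNAPII; points are single libraries, and the squares are the 14 h libraries without a treatment name. In DMSO total RNAPII the G1/S value goes from 0.58 at 16 h to -0.19 at 22 h, and the mitotic value from 0.11 to 0.45. At 19 h the total RNAPII mitotic value is lower in ATRi (0.44) than in DMSO (0.51), although the median of the gene ratios lies 0.02 above that of all genes.

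At each hour alone, the ATRi and DMSO libraries form 1 pair, so no replicate check is possible and no p is given. At 22 h total RNAPII was higher in ATRi over most genes: the median log2 ratio over 12000 genes was 0.50, with 505 genes at least 2-fold higher and 2 lower, against medians of 0.05 at 16 h and -0.03 at 19 h with 0 such genes. After centring on the median, 2 genes were at least 2-fold higher and 176 lower at 22 h. In Ser2 the medians were 0.06, 0.06 and 0.16, with 1, 0 and 1 genes at least 2-fold higher and 0 lower. The mean of the 3 hourly medians was 0.18 ± 0.29 (SD, n = 3 hours) in total RNAPII and 0.10 ± 0.06 in Ser2.

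Several gene groups lay on opposite sides at 16 h and 19 h. In total RNAPII, matrix genes lay 0.28 above the median gene at 16 h and at -0.15 at 19 h, immediate early genes 0.24 above and at -0.16, and p53 targets 0.16 above and at -0.08. CDKN1A had ratios of 0.58, -0.21 and 0.66 in total RNAPII and of 0.77, -0.07 and 0.54 in Ser2. G1/S genes lay at -0.12 at 16 h, -0.06 at 19 h and 0.22 at 22 h in total RNAPII, and at -0.10, -0.02 and -0.01 in Ser2. Mitotic genes lay 0.20, 0.02 and 0.32 above the median gene in total RNAPII, the 19 h value being at percentile 79.4 of the random lists matched on level and at 99.8 of those matched on length as well. With the trend with read density removed that value was 0.05 (95% interval 0.02 to 0.07).

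On the deposited scale the ratio differed with gene length. At 22 h the median total RNAPII ratio was 0.78 for genes under 10 kb, 0.62 for 10 to 30 kb, 0.43 for 30 to 100 kb and 0.18 above 100 kb. The shortest class exceeded the longest by 0.60 at 22 h and by 0.10 at 16 h, and differed from it by -0.12 at 19 h. In Ser2 the difference was 0.21, 0.07 and 0.20 at 16, 19 and 22 h. With the trend with read density removed, the 4 total RNAPII classes at 22 h lay at 0.00, 0.02, 0.01 and -0.02. The Ser2 classes lay between -0.03 and 0.01, so the difference was not kept at that hour. Read density is RPM per kb, so gene length is part of it. Removing its trend can take out a difference with length, and these values cannot tell length from density. Genes are not independent replicates, so no test was made.

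**Figure D3:**
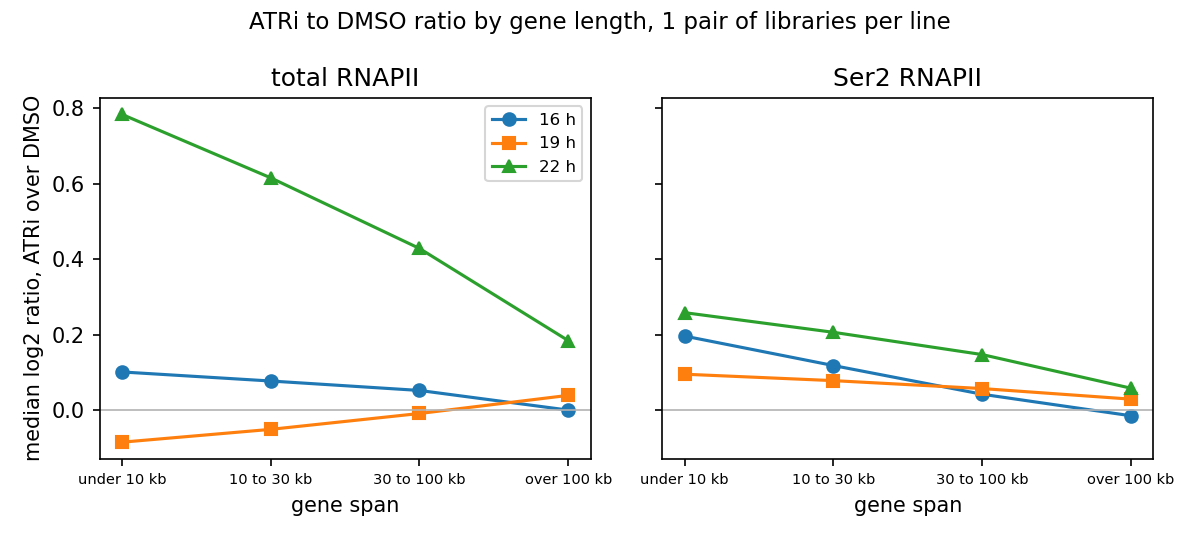
Median log2 ratio of ATRi to DMSO by class of gene span in kb, 1 line per hour, each from 1 pair of libraries, for total and Ser2 RNAPII. The 22 h total RNAPII line goes from 0.78 in genes under 10 kb to 0.18 in genes over 100 kb, and the 19 h line goes the other way, from -0.09 to 0.04. With the trend with read density removed, which is not drawn, the first of these lines goes from 0.00 to -0.02. Gene length is part of read density, so this does not tell the one from the other.

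The time course set the DMSO libraries against the 14 h library, which has no vehicle name. At 19 h signal was higher over most genes, with a median log2 ratio of 0.88 in total RNAPII and 0.83 in Ser2, against 0.26 and -0.07 at 16 h and -0.01 and 0.10 at 22 h. Relative to the median gene, mitotic genes lay at 0.15, 0.47 and 0.53 in total RNAPII at 16, 19 and 22 h, and at 0.07, 0.52 and 0.49 in Ser2. G1/S genes lay at 0.15, -0.07 and -0.60 in total RNAPII and at -0.15, -0.10 and -0.42 in Ser2. Histones lay at 0.29, 0.44 and 0.33 in total RNAPII and at -0.14, 0.56 and 0.33 in Ser2, where the 16 h value turned to 0.40 with the trend with read density removed. Immediate early genes lay at -0.15, -0.08 and -0.37 in total RNAPII and at -0.68, -0.03 and -0.46 in Ser2. With that trend removed, mitotic medians were 0.04, 0.16 and 0.53 in total RNAPII and 0.11, 0.24 and 0.47 in Ser2. The G1/S medians at 19 h were then -0.30 in both antibodies. Those of immediate early genes lay between -0.37 and -0.24 at every hour, so their differences between hours were mostly not kept. These are values of single libraries, with no replicate check.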

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

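No explanation was tested for the results in this part. Replication-dependent histone genes differed between hours: relative to the median gene their ATRi to DMSO median lay at 0.19 (total) and 0.32 (Ser2) at 16 h and at -0.25 and -0.11 at 19 h, a gap of 0.434 averaged over the antibodies. Ribosomal protein genes lay at -0.27 and -0.19 at 16 h and at 0.38 and 0.17 at 22 h, a gap of -0.505. Spliceosomal snRNA genes lay at 0.36 and 0.45 at 16 h, at -0.33 and -0.23 at 19 h and at -0.34 and -0.69 at 22 h, gaps of 0.681 and 0.918. These stood out because both antibodies lay on one side at the earlier hour and on the other at the later. With the trend with read density removed, the following sides were not kept in both antibodies: histones lay at 0.01 and -0.02 at 16 h, ribosomal protein genes at -0.02 and -0.01 at 22 h and snRNAs at 0.10 and -0.04 at 16 h. The differences were not tested, since each hour has 1 pair of libraries per antibody.

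Mitochondrial genes, which RNAPII does not transcribe and which were left out of all comparisons, held up to 334 RPM (Ser2, ATRi, 16 h) and as little as 53.9 RPM (Ser2, ATRi, 19 h), above the floor of 3 reads in every library.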

How the results depend on the processing

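The alternatives with a background density, read-density trend, edgeR, DESeq2, length-matched lists and list tests beyond centring were added after the data were seen. In a design of 1 library per group, the 3 hourly pairs limit the tests, and depth (303 to 1623 reads in the median gene) limits weakly read genes. The G1/S and mitotic calls between hours kept their side in every alternative but the estimated correlation, under which 0 lists were called in any of the 5 comparisons. Where no cause is named, the cause was not tested.

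For ATRi in total RNAPII, background subtraction gave 21 genes higher and 35 lower. For ATRi in Ser2, leaving out 1 hour in turn gave 0 to 846 higher and 0 to 6 lower, and DESeq2 gave 16 lower. Between hours in total RNAPII, a pseudocount of 5 gave 1 higher and 2 lower, background subtraction 32 and 18, trend removal 491 and 555, and DESeq2 24 and 26. Between hours in Ser2, quantile normalization gave 1212 and 1104, centring 1221 and 1262, trend removal 551 and 391, edgeR with TMM 1160 and 911, DESeq2 623 and 597, and background subtraction 185 lower; scalings that set the median near 0 move these counts by construction. The median change between hours was -0.26 in the DMSO pair and 0.14 in the ATRi pair for total RNAPII, and 0.16 and 0.25 for Ser2.

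Lists called for ATRi in total RNAPII numbered 3 after background subtraction, and 3 at the lowest when an hour was left out. For Ser2 relative to total they numbered 2 with centring, quantile normalization or trend removal, and 5 to 7 without an hour. Between hours in total RNAPII they numbered 4 after background subtraction and 5 after trend removal. Some lists changed side. With the trend removed the adjusted p was 0.994 for immediate early and 0.726 for fragile site genes (ATRi, total), 0.342 for matrix genes (ATRi, Ser2) and 0.345 for ribosomal protein genes (hours, Ser2). Leaving out each hour in turn it was 1.6e-04 to 0.960 for fragile site and 0.0285 to 0.960 for machinery genes (total) and 5.1e-22 to 0.267 for snRNAs (Ser2), the highest and the change of side being without 22 h. Over all alternatives but the estimated correlation, the adjusted p ranged from 4.65e-06 to 0.994 for immediate early, 3.0e-10 to 0.960 for fragile site, 1.5e-13 to 0.914 for matrix and 6.6e-07 to 0.345 for ribosomal protein genes.

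At a 1.5-fold threshold the genes higher and lower in ATRi were 62 and 13, 2 and 1, and 4890 and 108 in total RNAPII at 16, 19 and 22 h, and 171 and 1, 7 and 3, and 168 and 6 in Ser2; a lower threshold admits more by construction. At 22 h in total RNAPII centring gave 2 higher and 176 lower, and the genes above the median level 149 and 0; for Ser2 at 16 h those genes gave 0 higher. With quartiles of length, the shortest minus the longest genes was -0.11 (total, 19 h), 0.54 (total, 22 h) and 0.18 (Ser2, 22 h). Against random lists matched on length as well, the percentile turned to 0.020 for histones (ATRi, total, 22 h), and against 14 h in DMSO to 99.9 for histones (Ser2, 16 h), 0.790 for ribosomal protein genes (total, 16 h) and 0.020 for them (Ser2, 19 h). All such percentiles were sorted as below, within or above the central 95% of the random lists. Of them 178 kept their class, 41 moved into the central range and 17 out of it. The 178 include percentiles that crossed the middle within that range, such as heat shock genes (ATRi, total, 22 h) from 77.5 to 12.5.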

Other observations

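All tests in this part were chosen after the result was seen. Ribosomal protein genes lay on opposite sides at 16 h and 22 h: 1 of 60 lay above the median gene in total RNAPII and 7 of 60 in Ser2, while at 22 h 60 of 60 and 57 of 60 did. With the trend with read density removed the 16 h medians stayed at -0.34 and -0.36, but those at 22 h were -0.02 and -0.01, so the 22 h side was not kept. RPS13, for example, had total RNAPII ratios of -0.34, 0.12 and 1.08 at 16, 19 and 22 h. Spliceosomal snRNA genes, short noncoding genes read by RNAPII, went the other way, with 7 of 7 above the median gene at 16 h in both antibodies and 0 of 7 at 19 h and 22 h. RNU4-2 had Ser2 ratios of 0.52, -0.20 and -0.76. With that trend removed the snRNA medians at 16 h were 0.10 in total RNAPII and -0.04 in Ser2, while those at 19 h and 22 h stayed below 0.

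Several p53 target genes had their largest Ser2 ratios at 16 h. CDKN1A lay at 0.77, GADD45A at 0.72, BBC3 at 0.68 and PLK3 at 0.52, and the p53 target list lay 0.24 above the median gene, with 17 of 21 above it. At 19 h these genes lay at -0.07, -0.10, -0.03 and 0.06. WEE1, the kinase that holds back mitotic entry, had ratios of 0.47, -0.14 and 1.00 in total RNAPII and 0.42, -0.10 and 0.38 in Ser2. IL6 had total RNAPII ratios of 0.04, 0.02 and 1.41, so its mean rests on 22 h.

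Total RNAPII was higher in ATRi over most genes at 22 h. A difference in depth as such is argued against, since RPM already divides by the library total. For the same reason thinning the pair to the same total could not move the median log2 ratio, which was 0.504. The total RNAPII pair at 19 h, with 46533646 (ATRi) and 35871568 (DMSO) reads, had a median of -0.026. A larger share of immunoprecipitated over background reads in the ATRi library may be the cause: the median went from 0.05 in the lowest quartile of read density to 0.842 in the highest. After subtraction of a background density it went from 0.291 to 0.935, so a rise with read density remained. More RNAPII on genes may equally be the cause, and the Ser2 median at that hour was 0.163. A larger share of immunoprecipitated reads and more RNAPII on genes cannot be told apart without a spike-in.

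The total RNAPII differences at 16 h and 19 h ran opposite ways across genes (Pearson r = -0.37 across 12000 genes, which are not independent replicates). A trend with read density as the whole cause is argued against, since r was -0.246 with that trend removed (95% interval -0.26 to -0.23). Noise independent between genes is argued against as well, since it gives no such correlation between differences that share no library. The total difference at 16 h shares no library with that at 19 h, nor with the Ser2 difference at 19 h (r = -0.219, -0.24 to -0.19). These intervals, from resampled chromosomes, measure the spread over genes and not between libraries. A departure that many genes share within a single library is therefore not excluded. Whether chromatin shared by both antibodies of an hour, or a response to ATRi that changes with the hour, lies behind the opposite differences was not tested.

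Mitotic genes were higher relative to other genes in ATRi in total RNAPII. A trend with read density is argued against as the whole cause, since the camera adjusted p with that trend removed was 9.6e-16, within 9.6e-16 to 2.2e-05 over the alternatives other than the estimated correlation (0.930). That ATRi cells may be further on towards mitosis needs mitotic genes above 0 and G1/S genes below 0 in each pair, and 3 of 6 pairs had both. Judged on sign alone, the rule as first written, the other 3 pairs argue against it; the rule was changed after that outcome was seen, to ask for departures beyond the 95% interval of resampled members, and then 0 pairs do. The explanation is therefore left open, and that verdict depends on the changed rule.

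With 3 pairs there are 10 splits of 6 libraries, too few for a share under 0.05. For ATRi in total RNAPII the real split called 0 genes and the highest other 8733. That split parts only the 22 h pair and keeps both libraries of each other hour together, which points to a structure of the samples, the wide difference within the 22 h pair. At an unadjusted p under 0.05 the real split had 204 genes, and the highest other that parts all pairs had 1156. For Ser2 the real split called 0 and the highest other 62; at an unadjusted p under 0.05 they had 2655 and at most 2618, or at most 858 among others that part all pairs. For Ser2 relative to total the real split called 0 genes, which all 32 of 32 splits reach whatever the data, so that count decides nothing; the highest other also called 0, and at an unadjusted p under 0.05 the real split had 9 genes and the highest other 3429.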
